A study of Caenorhabditis elegans with 219 samples.

How the data were processed

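The samples are single cells of embryos of the N2 strain of Caenorhabditis elegans from the fertilized egg (1-cell stage) to the 16-cell stage. Per the labels' protocols, worms were kept at 20 °C, eggshells were weakened with enzymes, embryos were taken apart by hand, cells were lysed and frozen singly, and libraries of polyadenylated RNA were made with a SMARTer Ultra Low Input kit and Nextera XT. The kit does not mark strand and carries no molecular identifiers. Each of 219 samples has 1 table of genes and 1 coverage track; the coverage tracks were not used here, since the build of their coordinates is not stated and the tables hold the counts of the same libraries. Per the submitters' processing notes, TopHat2 2.0.11, SAMtools 1.3, bedtools and HTSeq were used with the builds ce10 and WBcel235, with no role or order given for any of them.

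The deposited tables have no header and list 31383 gene models with a whole-number count, a length and an RPKM value. The counts in the deposited tables are raw, as their totals differ between libraries and no scaling shows in them. The RPKM values in the deposited tables are the count divided by the length in kilobases and by 1 total per library; this total is 1.052 to 1.918 times the sum of the counts, by a factor that differs between libraries and has no stated source. A length of 2500 is repeated for 1350 models, which looks like a placeholder, and the RPKM of such a model is uncertain; they hold a median of 0.57% of counts. Coordinates are not in the tables: 27361 models were matched by name to the reference annotation of WBcel235, and chromosomes and positions come from that match.

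Total counts ran from 2542 to 3790868 per labelled library, with medians of 3139244 at the 1-cell, 2036165 at the 2-cell, 1945093 at the 4-cell, 1579928 at the 8-cell and 1214134 at the 16-cell stage. In 5 labelled libraries the total is under 100000. Intervals of shares and floors cover counting error only, since amplified reads are not independent molecules. A fold against a group at 0 was computed against a floor of 3 counts over the group. No 2 libraries have identical counts, and the most alike pair has a correlation of 0.9357 with a chi-square of 20.36 per degree of freedom.

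The labels name the cell for 165 samples and give the embryo as a number; 54 cells have no identity in the labels and enter no comparison. The replicate is the embryo; sister groups of 1 embryo enter a fit as separate values, with no block in the main test. Counts were summed and RPKM values averaged over the cells of 1 group in 1 embryo, and for comparisons between stages over all labelled cells of an embryo. Of the 6 embryos at the 16-cell stage, 2 have all 16 cells labelled. All groups of a stage entered 1 fit and shared an estimate of the spread, the 5 stages entered 1 fit, and a lineage was the mean of its groups. Genes at 10 RPKM or more in at least 3 values of a fit were tested. The comparisons, the tests written for them, the gene lists, the alternatives and the naming rule were fixed before the data were examined.

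The test written in advance was limma on log2(RPKM + 1), with a pseudocount of 1 RPKM. Since the tables hold counts, the test used is edgeR's quasi-likelihood test on counts with TMM scaling, a two-sided p and Benjamini-Hochberg adjustment, called at 0.05, and limma on log2(RPKM + 1) is given as an alternative. The earlier quasi-likelihood form of edgeR was fitted first, and its counts for all comparisons were seen, as were the 16-cell counts of the bias-adjusted form with its own dispersion. On simulated counts that first form made many false calls in some comparisons, 20 of 80 in the ABp versus ABa daughters, 118 of 162 in the ABp versus ABa granddaughters and 19 of 46 in the C versus P3 daughters, but 0 of 15 in E versus MS and 0 of 9 in C versus P3, so 7 forms were compared on 24 simulated data sets drawn from these libraries. False calls were 27.5% of 1700 with the earlier form, 56.1% of 4243 with adjusted deviances and their own dispersion, and 6.8% of 1331 with adjusted deviances and the trended negative binomial dispersion. By comparison this last share was 12% of 75 calls for the C versus P3 daughters, 9.2% of 445 for the P1 versus AB daughters, 8% of 199 for the ABp versus ABa daughters and 3.8% to 5.1% for the 4 others with calls. In the recovery tests described next, 11 of 99 calls were false in ABp versus ABa and 3 of 20 in the E versus MS daughters. The trended form was chosen on the simulations and not on the calls in the real data, and the earlier form is kept as an alternative. The simulated counts follow a negative binomial distribution with that same trend, so the choice is favoured by the way they were drawn.

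The gene tests of the first 12 comparisons were run on simulated data in which 200 genes were changed by 4- or 16-fold. The other comparisons and the Fisher tests of gene families were not simulated. For the 4-fold and the 16-fold genes edgeR recovered 59% and 84% in 16-cell versus 1-cell embryo means, 50.5% and 87% in P1 versus AB, 47.5% and 83% in the P1 versus AB daughters, 20% and 74% in EMS versus P2, 15% and 73% in ABp versus ABa, 0% and 15.2% in E versus MS, 0% and 12% in C versus P3, and 12% and 49.5% in the ABp versus ABa daughters. At the 16-cell stage it recovered 2% and 15.2% in the E versus MS daughters, 6% and 22% in the C versus P3 daughters, 0% and 0% in D versus P4, and 3% and 24% in the ABp versus ABa granddaughters. The simulated cell comparisons from the 8-cell stage on therefore had little power for single genes, and the D versus P4 test found none of the simulated changes.

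Gene lists were tested with camera on log2(RPKM + 1), with a preset correlation of 0.01 and again with the correlation estimated, adjusted over 327 pairs of list and comparison. The lists cover EMS and SKN-1-dependent zygotic genes, endoderm, MS mesoderm, and C and D lineage regulators, Notch and Wnt pathways, germ plasm, maternal RNA-binding regulators, eggshell, early zygotic transcripts, polarity, cell cycle, ribosomal proteins, mitochondrially encoded models and heat shock. Some genes stand in more than 1 list. The symbols written for the mitochondrial list did not match the tables, so 14 models with the mitochondrial prefix or the symbol ctb-1 were used, chosen after the identifiers were seen. Lists of sperm, adult intestine, muscle, epidermis, neuron and gonadal sheath genes mark other cell types. Families are symbols with 1 prefix and at least 15 tested members, compared with all genes by a one-sided Fisher's exact test. That test takes members as independent, which copies that share reads are not.

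The naming rule takes, in each of the first 12 comparisons, the 6 genes with the largest positive and the 6 with the largest negative log2 fold change among those with an adjusted p under 0.05, a mean of at least 25 RPKM on the higher side and every value of that side above every value of the other; other comparisons give 2 and 2. By chance 0.433% of genes separate 6 against 5 embryos and 0.794% separate 5 against 5. Up to 4 members of a described list are named as well, those with the smallest p. Genes with near-identical copies (med-1 and med-2, tbx-37 and tbx-38, hlh-25 and hlh-27, the fbxb and skr families) are uncertain, as are genes that overlap another on either strand.

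Cells with 1 embryo number come from 1 embryo, per the labels. Deviations from the group means were positively correlated in every 2- and 4-cell pair of the same embryo, with medians of 0.1738 and 0.09768, and less at the 8- and 16-cell stages (0.05371 and 0.0292), against -0.05238, -0.02754, -0.01463 and -0.006166 for cells of different embryos. Fits with the embryo as a block are therefore given, beside a result or with the dependence on the processing. At the 8- and 16-cell stages the chosen form with a block ended in an error inside edgeR, so the block was fitted there with the earlier form and with limma.

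Settings varied by plan were median-ratio scaling, no filter on low values, a pseudocount of 10 RPKM, array quality weights, each embryo left out in turn, the embryo as a block, the complete 16-cell embryos, and an estimated correlation for the lists; the pseudocount and the weights were run in limma, which uses them. Chosen after seeing the data were DESeq2, the earlier form and leaving out libraries under 100000 counts. So was running the block with the earlier form or limma. Limma itself was the test written in advance, and it became an alternative when edgeR took its place. Genes per cell were also counted at 5 counts or more after thinning to 400000 counts, and compared by two-sided exact permutation of the embryos. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.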

Results

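Polyadenylated RNA was sequenced from single cells of Caenorhabditis elegans embryos, the N2 laboratory strain, after each embryo at the 1-, 2-, 4-, 8- or 16-cell stage had been taken apart by hand. Each of the 219 samples is 1 cell. The labels name the cell for 165 of them, which come from 26 embryos and fall into 27 cell groups, and they leave 54 cells without an identity (1 at the 1-cell, 8 at the 8-cell and 45 at the 16-cell stage). P0 is the fertilized egg, AB and P1 are its daughters, ABa and ABp are the daughters of AB, and EMS and P2 are those of P1. At the 8-cell stage EMS has given MS and E, the founder of the intestine, and P2 has given C and the germline precursor P3, whose daughters at the 16-cell stage are D and P4. Groups hold 5 embryos at the 1- to 8-cell stages and 4 to 6 embryos at the 16-cell stage. Total counts per labelled library ran from 2542 to 3790868, with a median of 1450742.

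Cell groups were compared mostly over the same embryos on both sides, stages were compared over different embryos, and a mean ± SD is over embryos. In the tests a value is 1 cell group in 1 embryo. Lineages of several groups therefore enter with more values than embryos (10 and 10 from 5 embryos for the P1 and AB daughters, 11 and 12 from 6 for the C and P3 daughters), which the test without a block takes as separate. The series text says that most cell identities were worked out afterwards from these same transcriptomes. A difference between named cells is therefore partly built into the names, and this holds for every comparison between cells below.

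The number of genes seen in a cell fell as the embryo divided. A cell held 5768 ± 98.3 genes at 10 RPKM or more at the 1-cell stage (SD, n = 5 embryos), 5387 ± 195 at the 2-cell, 4980 ± 392 at the 4-cell, 3847 ± 468 at the 8-cell and 2863 ± 377 at the 16-cell stage (n = 6 embryos). The 16-cell value was below the 1-cell value (difference -50.36%, two-sided exact permutation test, p = 0.002165, 462 arrangements). When the labelled cells of each embryo were averaged first, 5752 ± 258 genes reached that level at the 16-cell stage (n = 6) against 5768 ± 98.3 at the 1-cell stage (n = 5), and the exact permutation p was 0.8983. That mean pools many libraries at the 16-cell stage and 1 at the 1-cell stage, so the similar counts do not show an unchanged content. Median depth was lower at the later stage, 1214134 against 3139244 counts per labelled library. With every cell thinned to 400000 counts, 3090 ± 373 genes at 5 counts or more were seen per cell at the 16-cell stage and 5889 ± 97.8 at the 1-cell stage, with 9 shallower 16-cell libraries left out. Without thinning these were 3238 ± 489 and 6810 ± 154.

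**Figure D1:**
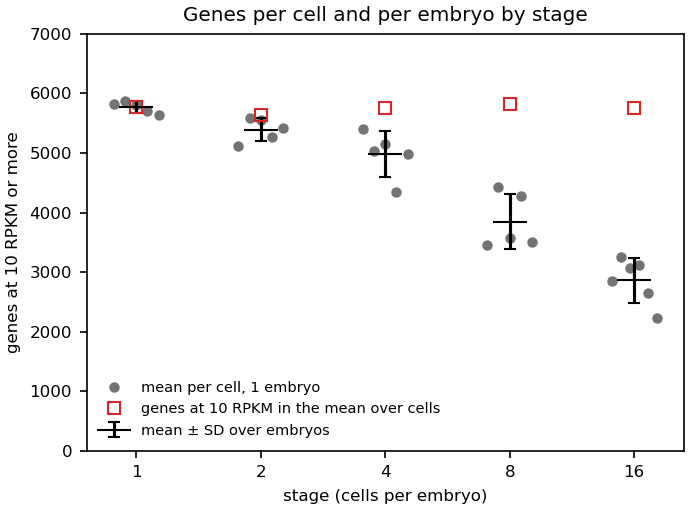
Genes at 10 RPKM or more (vertical axis) at each stage (horizontal axis, cells per embryo): each grey point is the mean per cell of 1 embryo, black bars are the mean and SD over embryos, and red squares count genes in the mean over an embryo's cells, averaged over embryos. The mean per cell falls from 5768 at the 1-cell to 2863 at the 16-cell stage, while the squares stay between 5639 and 5814. The squares pool more libraries at later stages.

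The first comparison set 16-cell against 1-cell embryos. Rises and falls are in library shares, not absolute amounts. Members of the fbxb family of F-box genes, which encode adaptors of ubiquitin ligases, led the increase. In the WBcel235 assembly fbxb-91 lies on chromosome II at 3749061 to 3750785. It averaged 438 ± 60.3 RPKM at the 16-cell stage (SD, n = 6 embryos), with 58527 counts against 0 in 5 1-cell embryos, at least 4287-fold higher when 3 counts over the group are taken as the floor. fbxb-49 (chromosome II, 1568514 to 1569600) averaged 260 ± 67.7 RPKM with 57625 counts against 0, at least 4221-fold higher. The genes fbxb-24 and fbxb-11 were at least 4110- and 3969-fold higher, also from 0. K05F6.4 (chromosome II, 1543482 to 1545415), at 336 ± 93.7 RPKM, and F40G9.9 (chromosome III, 170319 to 171717), at 324 ± 64.7 RPKM, had 0 counts at the 1-cell stage as well. Of 102 fbxb genes tested, 100 rose and 0 fell, against 30.19% of all genes rising (Fisher's exact test, adjusted p = 3.09e-48 over 54 family tests); across the other scalings and tools 99 to 101 rose. Reads from near-identical fbxb copies may have been shared, so the value of a single member is uncertain and members are not independent in the family test. A member absent from the egg passed the filter only through later stages, so it could not be called lower.

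Genes of the EMS cell and genes first transcribed in the embryo rose with them. In the list of EMS and SKN-1-dependent zygotic genes, 15 of 17 tested members rose and 0 fell, and the count adjusted over the list alone was also 15 and 0 (set test, adjusted p = 1.66e-11, and 0.00298 with an estimated correlation). sdz-33 reached 446 ± 156 RPKM (n = 6) from 0.1 ± 0.1 (n = 5), sdz-21 reached 363 ± 121, and sdz-30 reached 497 ± 116 from 0.1 ± 0.2. These genes depend on the maternal factor SKN-1. sdz-1 reached 330 ± 212 from 0 counts, at least 1943-fold higher. Among early zygotic transcripts 7 of 11 rose and 0 fell (set adjusted p = 0.000137, and 0.0374 with an estimated correlation; 7 and 0 adjusted over the list alone). They included pes-10, an early embryonic marker, at 537 ± 99.3 RPKM against 0.3 ± 0.3, vet-6 at 386 ± 64.2 against 0.1 ± 0.1, vet-2 at 550 ± 80.9 against 47.5 ± 19.4 and vet-1 at 893 ± 183 against 26.3 ± 33.7. Of 77 cytosolic ribosomal protein genes 63 rose and 0 fell (50 to 53 rose under other scalings and tools, and 70 over the list alone), with a set adjusted p of 9.87e-09 but 0.706 with an estimated correlation. Among them rpl-12 stood at 2621 ± 902 against 865 ± 200 RPKM.

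Many members of the lists of maternal transcripts fell. Among maternal RNA-binding regulators 17 of 21 fell and 0 rose (18 and 0 adjusted over the list alone; set adjusted p = 2.64e-08, and 0.0356 with an estimated correlation). oma-2, a zinc-finger regulator of the oocyte, went from 597 ± 196 (n = 5) to 53.7 ± 25 RPKM (n = 6), mex-3, a KH-domain protein, from 588 ± 112 to 38.4 ± 27.6, and spn-4 from 917 ± 150 to 189 ± 48.5. Of 20 germ plasm and P granule genes 11 fell and 0 rose (12 over the list alone), with a set adjusted p of 0.0001 and 0.152 with an estimated correlation. The Y-box protein gene cey-2 fell from 1204 ± 452 to 67.1 ± 39.1. pos-1, which belongs to both lists, fell from 1106 ± 251 to 291 ± 112. Eggshell and egg activation genes fell in 11 of 13 cases (12 over the list alone; set adjusted p = 1.97e-05, and 0.0661 with an estimated correlation), among them cbd-1, a chitin-binding eggshell protein, from 338 ± 170 to 7.7 ± 6.4 RPKM. The steepest falls by the naming rule were F43D2.2, from 71.0 ± 24.5 RPKM and 1722 counts to 0, at least 2612-fold lower, Y17G9B.9, from 134 ± 46.3 RPKM to 1 count, C56C10.10, from 101 ± 21.7 RPKM to 2 counts, and F32D1.6, from 167 ± 27.6 to 0.1 ± 0.1 RPKM. T14B4.5 and K11H3.4 fell from 57.7 ± 36.4 and 29.8 ± 18.1 RPKM to 0 counts.

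Of 7860 genes tested, 2373 were higher and 1375 lower at the 16-cell stage (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). The median gene shifted by 0.33 on the log2 scale, by 0.16 with median-ratio scaling and by -0.41 with limma on RPKM. Calls near that size can depend on the scaling. Median-ratio scaling gave 2177 higher and 1589 lower, which kept the balance. Limma, which changes test and scaling together, gave 1689 and 2630. Wnt pathway genes (5 of 15 higher) were 2 higher and 3 lower with limma, so no direction is given for them. Ribosomal RNA made up 2.7% ± 0.794 of counts at the 16-cell (n = 6) and 0.586% ± 0.324 at the 1-cell stage (n = 5).

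Neighbouring stages were compared as well. From the 1- to the 2-cell stage 14 genes passed the test, 6 higher and 8 lower. pri-2, a DNA primase subunit, rose from 83.3 ± 35.2 to 428 ± 214 RPKM (n = 5 and 5, adjusted p = 0.0208 by edgeR) and F19F10.10 from 23.7 ± 8.1 to 96.2 ± 39.0. F07H5.13 fell from 37.6 ± 35.2 to 0.6 ± 0.8. The other lower calls were led by RNA from the mitochondrial genome: 4 of 14 mitochondrially encoded gene models fell (14 adjusted over the list alone; set adjusted p = 7.93e-26, and 0.0374 with an estimated correlation), among them ctb-1, cytochrome b, from 2000 ± 787 to 526 ± 278 RPKM, and the model MTCE.35, from 468 ± 172 to 111 ± 72.6. The mitochondrial share here is that of all mitochondrial models in the counts without ribosomal RNA. It was 1.98% ± 0.769 at the 1-cell, 0.552% ± 0.349 at the 2-cell and 1.88% ± 0.735 at the 16-cell stage (1- against 2-cell, two-sided exact permutation p = 0.007937 of 252 arrangements). A further 1-cell library, which has no cell label and enters no test, held 0.405% of all its counts (95% Wilson interval 0.397 to 0.414). By the same measure this is below the labelled 1-cell libraries (1.02 to 2.822) and within the range of the 2-cell libraries (0.191 to 1.163). The 14 calls became 2 without a filter on low genes, 1 with the earlier form of the test, 116 higher and 84 lower with DESeq2, 3 and 4 with limma and 467 and 781 with array quality weights in limma. Leaving out 1 embryo gave 60 (2-cell embryo 5), 47 (1-cell embryo 5), 3 (2-cell embryo 1), 1 (1-cell embryo 2 or 2-cell embryo 2) or 0 (1-cell embryo 1 or 4, 2-cell embryo 3 or 4).

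From the 2- to the 4-cell stage 107 genes passed, 104 of them higher. Y75B12A.2 (chromosome V, 15109560 to 15110443) went from 0 counts to 96.6 ± 23.7 RPKM (n = 5), at least 536-fold higher, and Y60A9.2 from 0 counts to 81.6 ± 79.9, at least 361-fold. Among EMS and SKN-1-dependent genes 5 of 17 rose (9 rose and 1 fell over the list alone; set adjusted p = 4.18e-08, and 0.0153 with an estimated correlation), with sdz-1 at 136 ± 54.9 against 0.7 ± 1.1 RPKM. Early zygotic transcripts rose in 4 of 11 cases (7 over the list alone; set adjusted p = 1.29e-12, and 0.000365 with an estimated correlation), with pes-10 at 27.6 ± 19.5 against 0.1 ± 0.1 and tbx-32, a T-box factor, at 23.4 ± 21.8 against 0.1 ± 0.1. The eggshell list was lower as a set (adjusted p = 2.02e-07, and 0.0234 with an estimated correlation) although 0 of its 13 members passed singly. The lower calls were dnj-27, a DnaJ-domain protein, from 93.6 ± 31.5 to 28 ± 6.7 RPKM and, chosen after their values were seen, F43D2.2 and K10D6.4. DESeq2 called 298 higher and 43 lower, limma 58 and 5, and limma with a pseudocount of 10 RPKM 34 and 6.

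From the 4- to the 8-cell stage 475 genes rose and 93 fell. sdz-13 went from 0 counts to 124 ± 23.2 RPKM, at least 2075-fold higher, and fbxb-41 from 0 counts to 87.8 ± 54.4, at least 1253-fold. med-2, a GATA-type factor of the EMS cell (chromosome III, 6884503 to 6885027), went the other way, from 39.9 ± 23.3 RPKM to 0 counts, at least 509-fold lower, and Y53H1A.2 fell from 179 ± 91.3 to 0.5 ± 1.1. Of 17 EMS and SKN-1-dependent genes 10 rose and 1 fell (14 and 1 over the list alone; set adjusted p = 2.52e-13, and 0.0015 with an estimated correlation). REF-1 family genes, basic helix-loop-helix targets of Notch, appeared at this stage, hlh-27 with 26.9 ± 7.0 RPKM and 2458 counts against 0, at least 557-fold higher. In total 5 of 10 genes of the Notch list rose (set adjusted p = 0.00169, and 0.1 with an estimated correlation). Calls with no filter on low genes were 323 and without 4-cell embryo 1 they were 375, while limma called 436 higher and 349 lower, and 406 and 445 with a pseudocount of 10 RPKM.

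From the 8- to the 16-cell stage 617 genes rose and 448 fell, against a shift of the median gene of 0.21 on the log2 scale. upb-1, a beta-ureidopropionase, went from 0 counts to 45.5 ± 27.9 RPKM (n = 6), at least 1730-fold higher, and pgp-2, an ABC transporter of intestinal granules, from 1 count to 33.4 ± 24.2 RPKM. tbx-32 fell from 45.7 ± 39.0 RPKM (n = 5) to 1 count and F32D1.6 from 28.5 ± 20.3 to 0.1 ± 0.1. Maternal RNA-binding regulators fell in 8 of 21 cases and rose in 0 (9 over the list alone; set adjusted p = 2.1e-07, and 0.0495 with an estimated correlation), with mex-3 at 38.4 ± 27.6 against 281 ± 133 RPKM. The balance turned in several alternatives: limma on RPKM called 653 higher and 1307 lower, DESeq2 490 and 775, no filter on low genes gave 272 and 399, leaving out libraries under 100000 counts 417 and 614, and the complete 16-cell embryos alone 122 and 404. It also turned without 16-cell embryo 3 (365 and 580), 6 (365 and 539) or 7 (339 and 539) and without 8-cell embryo 1 (341 and 538), 3 (294 and 510) or 6 (370 and 547), but not with median-ratio scaling (528 and 503) or the earlier form of the test (512 and 384).

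**Figure D2:**
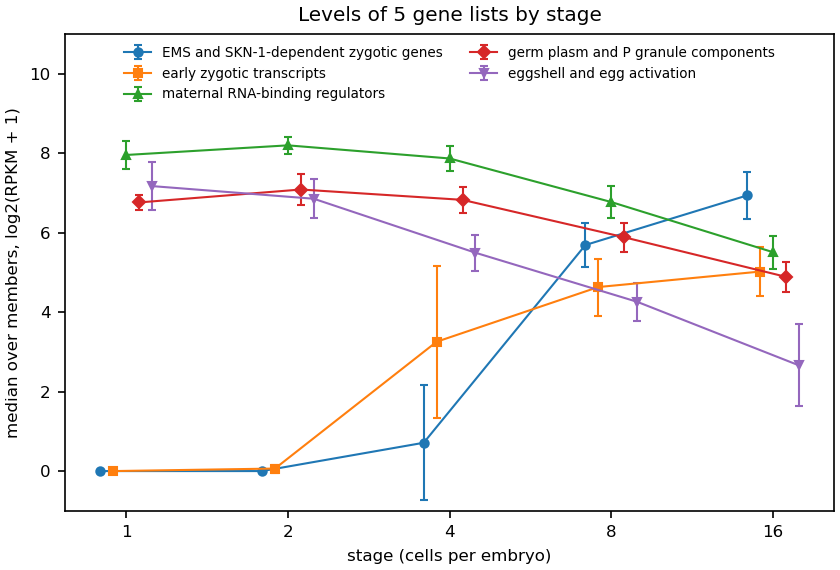
Median over a gene list of log2(RPKM + 1) in the mean of an embryo's cells (vertical axis) at each stage (horizontal axis, cells per embryo), for 5 gene lists; points are means over 5 embryos (6 at the 16-cell stage) and bars the SD. The EMS and SKN-1-dependent list goes from 0 at the 1-cell to 6.93 at the 16-cell stage, and the maternal RNA-binding list from 7.95 to 5.51.

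The next comparison asked whether the daughters of the fertilized egg differed. Between P1 and AB no gene passed. edgeR called 0 of 6058 genes with 5 embryos on each side, DESeq2 called 11 and limma on RPKM called 0, and 267 genes had an unadjusted p under 0.05. chs-1, the eggshell chitin synthase, read 53.9 ± 30.7 RPKM in P1 and 9.3 ± 7.8 in AB (adjusted p = 0.821). For rps-0 the values were 123 ± 68.3 and 40.4 ± 16.9 (adjusted p = 0.793). The eggshell list was higher in P1 as a set (adjusted p = 0.00018, but 0.284 with an estimated correlation), as were ribosomal protein genes (2.38e-09, but 0.544) and mitochondrially encoded models (0.0343, but 0.897). In simulated libraries of this comparison 50.5% of genes changed by 4-fold and 87% of those changed by 16-fold were recovered.

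At the 4-cell stage the daughters of P1 were set against the daughters of AB. sdz-1 stood at 271 ± 110 RPKM (SD, n = 5 embryos) in the P1 daughters and 0.4 ± 0.5 in the AB daughters (adjusted p = 0.031). It was 1 of 3 genes to pass. The others, chosen after their values were seen, were T04A8.7, higher, and eel-1, a ubiquitin ligase, lower. Maternal transcripts leaned the same way without passing singly: oma-2 read 609 ± 204 against 218 ± 99.8 RPKM (adjusted p = 0.0519), puf-11, a Pumilio-family protein, 287 ± 86.7 against 104 ± 52.4, and pgl-3, a P granule protein, 86.4 ± 37.1 against 5.7 ± 12.2. As sets the EMS list (adjusted p = 0.000325, and 0.0356 with an estimated correlation), the maternal RNA-binding list (6.88e-06, but 0.284), the germ plasm list (0.00707, but 0.393) and the eggshell list (7.73e-07, but 0.152) were higher in the P1 daughters, with 1, 5, 2 and 5 members higher over the list alone. With the embryo as a block the EMS list had an adjusted p of 0.0792 and the eggshell list 0.0276 with an estimated correlation, and 52 genes were called higher and 13 lower. The 3 calls became 14 higher and 2 lower with median-ratio scaling, 72 and 31 with limma and 122 and 99 with DESeq2; they were 69 without embryo 1, 11 without embryo 4 and 0 without embryo 2, 3 or 5.

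Within the P1 daughters, EMS was compared with P2, the germline precursor. EMS held transcripts that P2 lacked. AH10.2 (chromosome V, 14156768 to 14157656) averaged 363 ± 135 RPKM in EMS (SD, n = 5) with 3258 counts against 0 in P2, at least 871-fold higher. vet-1 stood at 126 ± 35.9 RPKM against 0 counts, at least 528-fold, tbx-32 at 93.7 ± 87.3, at least 366-fold, ccch-2, a CCCH-type zinc finger gene, at 129 ± 155, at least 310-fold, and Y60A9.2 at 141 ± 165, at least 268-fold. Y75B12A.2 stood at 386 ± 94.9 against 0.2 ± 0.4. Of 7 EMS and SKN-1-dependent genes 2 passed and all 7 passed over the list alone, each higher in EMS (set adjusted p = 1.27e-10, and 0.000597 with an estimated correlation): sdz-1 at 541 ± 219 RPKM against 0.4 ± 0.4 and med-2 at 159 ± 93 against 0 counts, at least 277-fold higher. med-1, its near-identical neighbour in sequence, read 64.4 ± 48.3 RPKM against 0 counts (adjusted p = 0.183), and reads may be shared between the pair. Early zygotic transcripts were higher in 3 of 9 cases (7 over the list alone; set adjusted p = 5.52e-12, and 0.00298 with an estimated correlation). The single gene higher in P2 was F55D12.5, at 47.9 ± 30.5 against 0.4 ± 0.8 RPKM (adjusted p = 0.0291). The test called 21 genes higher in EMS and 1 higher in P2. It called 1 without embryo 3, 14 without embryo 1 or 2 and 13 without embryo 5, and DESeq2 called 140 and 28.

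ABp, which receives a Notch signal from P2, was compared with its sister ABa. edgeR called 0 of 6601 genes with 5 embryos on each side, DESeq2 called 25 higher and 27 lower, limma called 0, and 219 genes had an unadjusted p under 0.05, fewer than chance alone gives. Without embryo 1 edgeR called 1. The Wnt list was lower in ABp as a set (adjusted p = 0.0329, but 0.351 with an estimated correlation and 0.0742 with the embryo as a block), with cwn-1, a Wnt ligand, at 0 counts in ABp and 29 ± 50.1 RPKM in ABa. In simulation 73% of 16-fold and 15% of 4-fold changes were recovered here, with the same limits as for P1 versus AB.

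**Figure D3:**
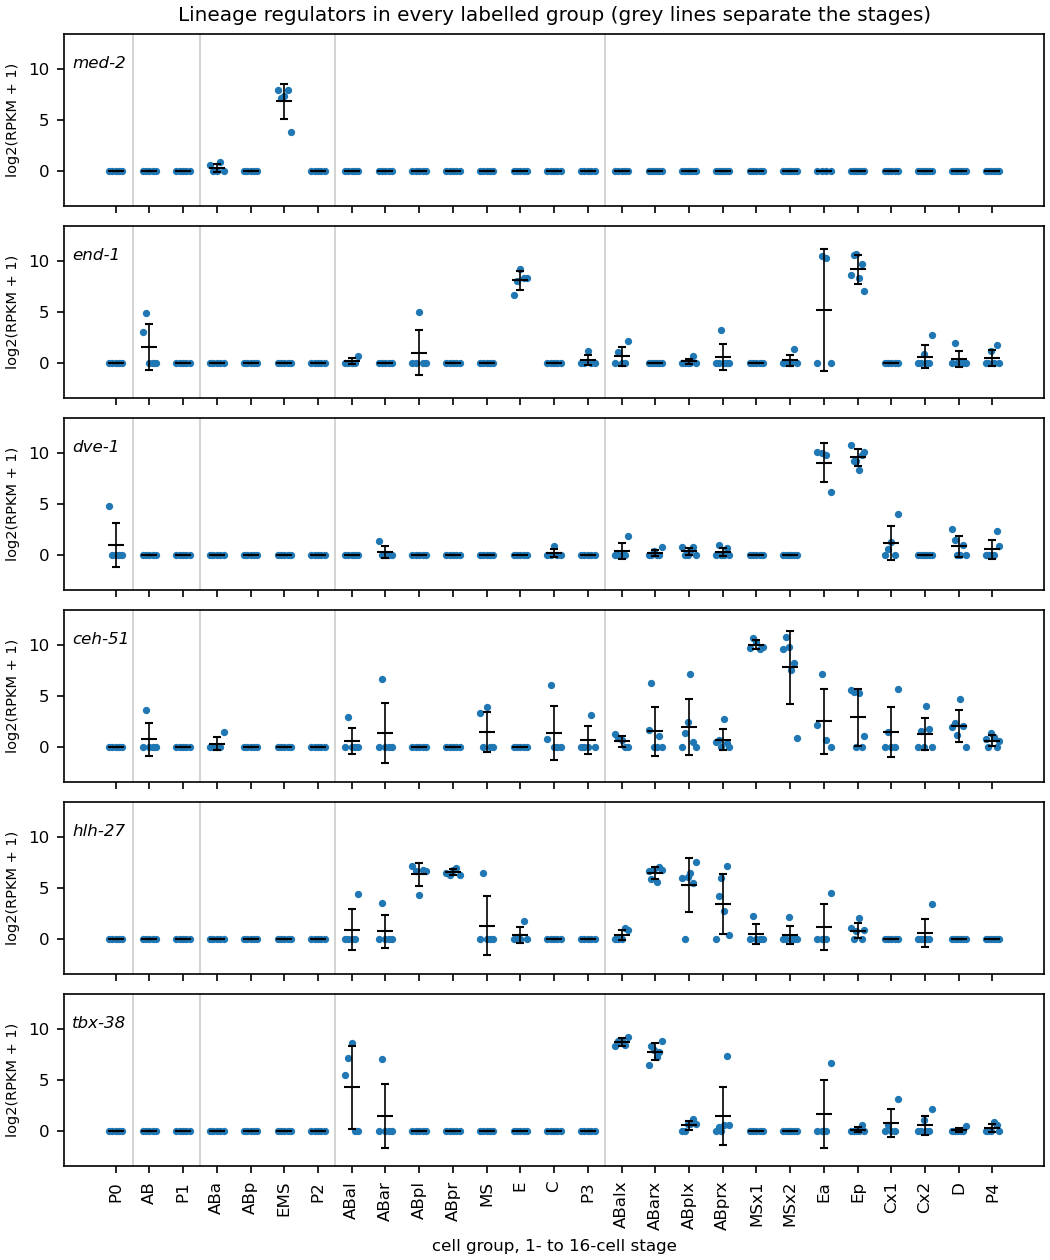
Level of 6 lineage regulators as log2(RPKM + 1) (vertical axis) in the labelled cell groups (horizontal axis); each point is 1 embryo, and bars are the mean and SD of the log values. Group means on the RPKM scale are 159 for med-2 in EMS, 323 for end-1 in E, 1119 for ceh-51 in MSx1 and 446 for tbx-38 in ABalx.

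At the 8-cell stage E, the founder of the gut, was compared with its sister MS. The endoderm genes end-3 and end-1, which encode GATA-type factors, read 550 ± 296 and 323 ± 184 RPKM in E (SD, n = 5) against 0.2 ± 0.3 RPKM and 0 counts in MS, the last at least 413-fold. Neither passed over all genes (adjusted p = 0.166 and 0.292), 2 of 3 endoderm regulators passed over the list alone, and the list was higher in E as a set (adjusted p = 5.06e-11, and 6.35e-06 with an estimated correlation). The genes that passed and separated every embryo were others. rpn-5, a proteasome lid subunit, stood at 179 ± 106 against 5.8 ± 5.4 RPKM (adjusted p = 0.0144) and cts-1, citrate synthase, at 545 ± 234 against 82.6 ± 74.4 (adjusted p = 0.0187). T06D10.2 was lower in E at 110 ± 46.8 against 494 ± 267 (adjusted p = 0.0144). In all 2 genes were higher and 7 lower in E, one of the lower being the ribosomal RNA model rrn-3.56, chosen after its values were seen. The MS library of embryo 1 had 58985 counts, 70.3% of them ribosomal RNA (95% Wilson interval 69.9 to 70.7). Without libraries under 100000 counts 1 gene was higher and 2 lower, without embryo 1 the count was 0 and without embryo 3 or 6 it was 2. DESeq2 called 337 and 245, limma 6 and 0, median-ratio scaling 4 and 16, and the earlier form of the test 5, or 0 with the embryo as a block.

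C was compared with P3, the germline precursor of that stage. C held early zygotic transcripts that were near 0 in P3. pes-10 stood at 242 ± 148 RPKM in C (n = 5) against 1.4 ± 2.0 in P3 (adjusted p = 3.11e-05), vet-1 at 145 ± 149 against 0.7 ± 1.0 and vet-2 at 161 ± 102 against 6.7 ± 11.1. In the early zygotic list 3 of 9 members passed, all higher in C (3 over the list alone; set adjusted p = 0.00755, but 0.169 with an estimated correlation). By the naming rule ZK673.5 (chromosome II, 10461507 to 10461947) was at 388 ± 217 against 0 counts, at least 427-fold higher, Y46G5A.28 at 236 ± 144 against 0.5 ± 1.0, Y44A6C.2 at 298 ± 313 against 0.9 ± 0.9, and nhr-10, a nuclear hormone receptor, at 172 ± 87.3 against 0.4 ± 0.8. cnk-1, a scaffold of Ras signalling, and pab-2, a poly(A)-binding protein, passed with 28.6 ± 56.8 and 71.5 ± 77.1 RPKM in C, but not with the earlier form of the test or with limma. Eggshell genes were lower in C as a set (adjusted p = 4.01e-06, and 0.00714 with an estimated correlation), with cbd-1 at 42.3 ± 56.4 against 214 ± 55.7 RPKM, though 0 of 12 members passed. Higher in P3 were F27C8.6, at 1066 ± 245 against 412 ± 231 RPKM, and, chosen after their values were seen, C01G10.10 and K07C5.6. The test called 94 genes higher and 3 lower in C. The earlier form of the test called 57, and 54 with the embryo as a block. The count was 45 without embryo 1, 37 without embryo 2 and 62 without embryo 3, DESeq2 called 453 and 143 and limma 45 and 28, and the balance turned to 31 and 41 with a pseudocount of 10 RPKM in limma.

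The granddaughters of AB that descend from ABp were compared with those from ABa. The REF-1 family gene hlh-25 (chromosome II, 5535239 to 5536405) averaged 43.0 ± 15.9 RPKM in ABpl and ABpr (n = 5) with 717 counts against 1 in ABal and ABar (adjusted p = 0.0319), and it was the single gene to pass. Of the same family, hlh-26 read 138 ± 168 against 0.1 ± 0.1 RPKM and hlh-29 20.7 ± 13.9 against 0 counts. On the ABa side tbx-38, a T-box factor repressed by Notch, read 72.2 ± 91.8 against 0 counts. None of these 3 passed over all genes. Of 11 genes in the joint list of Notch pathway and REF-1 family genes 6 were higher and 1 lower over the list alone (set adjusted p = 3.99e-15, and 4.98e-05 with an estimated correlation). hlh-25 lost its call without a filter on low genes, with the earlier form of the test, where the count was 0 with and without the embryo as a block, and when embryo 1, 2, 3 or 4 was left out (0 calls without 2, 3 or 4, and 2 without 6). limma called 7 genes and DESeq2 281.

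Between ABar and ABal edgeR called 0 of 7271 genes, DESeq2 189 and limma 0, with 273 at an unadjusted p under 0.05. Between ABpr and ABpl mex-5, a maternal CCCH zinc-finger protein, was lower in ABpr at 5.8 ± 7.8 against 189 ± 145 RPKM (n = 5, adjusted p = 0.0112). It was the single call, and it was lost without embryo 3, 4 or 6 and with the embryo as a block (earlier form of the test).

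At the 16-cell stage the E and MS daughters were compared. dve-1, a homeodomain factor (chromosome X, 427035 to 433812), averaged 794 ± 401 RPKM in Ea and Ep (SD, n = 6 embryos) with 9992 counts against 0 in the MS daughters, at least 5472-fold higher. end-1 stood at 806 ± 693 against 0.1 ± 0.3 RPKM but was 0 in Ea of embryos 1 and 8. The latter held tbx-38 at 101 RPKM. elt-7, a GATA-type factor of the gut, stood at 747 ± 575 against 0.1 ± 0.2. Of the endoderm regulators 3 of 4 passed and 4 over the list alone (set adjusted p = 3.35e-18, and 1.37e-06 with an estimated correlation). The MS daughters held ceh-51, a homeobox factor of mesoderm, at 876 ± 464 against 29.3 ± 26.6 RPKM (adjusted p = 0.042) and hlh-1, the MyoD homologue of body muscle, at 269 ± 216 against 0.1 ± 0.1 (adjusted p = 0.00958). Of the MS regulators 2 of 5 passed and 4 over the list alone (set adjusted p = 3.04e-07, and 9.42e-05 with an estimated correlation).

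Among other genes named by the rule, acs-22, an acyl-CoA synthetase, stood at 256 ± 146 RPKM in the E daughters against 0 counts, at least 3073-fold higher, and T19B10.2 at 299 ± 159 against 0 counts, at least 2213-fold. The acid phosphatase family member acp-2 stood at 949 ± 728 against 0.2 ± 0.3, F37C4.6 at 253 ± 132 against 1 count and F59A1.10 at 354 ± 197 against 0.1 ± 0.2. On the MS side ten-1, a teneurin, stood at 113 ± 40.6 against 0.1 ± 0.1 RPKM, Y46G5A.8 at 873 ± 666 against 4.7 ± 9.8 and dct-13 at 539 ± 342 against 23.7 ± 31.2. The test called 148 genes higher and 48 lower in the E daughters among 8397; acs-22, T19B10.2, F59A1.10 and ten-1 overlap genes on the opposite strand, and the kit does not mark strand. Counts moved with the tool, 462 and 237 with the earlier form, 223 and 92 with limma, 663 and 933 with DESeq2, and 246 and 92 with the embryo as a block (earlier form). Leaving out embryo 1, 6 or 7 gave 108, 130 or 118.

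The C daughters differed from the P3 daughters, D and P4, more widely. In the fbxb family, which had risen since the 1-cell stage, 72 of 103 genes were higher in the C daughters and 0 lower (10.93% of all genes higher, Fisher's exact test, adjusted p = 2.12e-44 over 60 family tests; 45 to 81 higher and up to 2 lower under other scalings and tools). Of 17 skr genes, relatives of the ubiquitin ligase adaptor Skp1, 8 were higher and 0 lower (adjusted p = 0.0039; 7 to 11 and up to 1 under other scalings and tools). Of 38 histone genes 12 were higher and 1 lower (adjusted p = 0.00601; 9 to 19 and 1 to 2). skr-15 stood at 1746 ± 2983 RPKM in the C daughters (SD, n = 6) against 9.1 ± 7.9, skr-8 at 1493 ± 1393 against 8.3 ± 6.8 and skr-12 at 479 ± 508 against 1.9 ± 1.9, with reads possibly shared among them. The chitinase gene cht-1 stood at 332 ± 214 against 0.4 ± 0.7, C05D12.5 at 952 ± 1265 against 0.8 ± 0.7 and ZC239.21 at 296 ± 217 against 0.8 ± 1.5. EMS and SKN-1-dependent genes were higher in 9 of 15 cases and lower in 1 (10 and 1 over the list alone; set adjusted p = 4.24e-07, and 0.00438 with an estimated correlation). Early zygotic transcripts were higher in 4 of 8 (4 over the list alone; 3.73e-06, and 0.00298), vet-6 at 328 ± 188 against 42.6 ± 94.6 RPKM.

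Lists of maternal transcripts were higher in the P3 daughters. Whether these transcripts were kept or newly made was not tested. Maternal RNA-binding regulators were higher there in 8 of 20 cases and lower in 0 (15 over the list alone; set adjusted p = 7.13e-14, and 0.000597 with an estimated correlation). The germline RNA-binding protein gene daz-1 stood at 313 ± 99.2 RPKM against 0.7 ± 1.1 in the C daughters, puf-3 at 255 ± 165 against 0.2 ± 0.4 and spn-4 at 1120 ± 460 against 74.2 ± 109. Germ plasm genes were higher in 6 of 20 cases (12 over the list alone; set adjusted p = 1.27e-07, and 0.0112 with an estimated correlation), with car-1, a P granule RNA-binding protein (chromosome I, 12904470 to 12906040), at 343 ± 152 against 1.2 ± 2.0. Also higher there were W05F2.3, at 1093 ± 449 RPKM against 1 count, and tdc-1, tyrosine decarboxylase, at 178 ± 185 against 0.1 ± 0.1. So were ubc-20, a ubiquitin-conjugating enzyme, at 551 ± 224 against 1.2 ± 1.5, gyg-2, a glycogenin, at 662 ± 367 against 13.4 ± 22.9, and C36B1.11 at 1063 ± 656 against 19.2 ± 22.1. Of 8397 genes, 918 were higher and 393 lower in the C daughters. Median-ratio scaling in the same test gave 623 and 682, so the balance of directions turned with that change of scaling. Limma gave 459 and 802 and DESeq2 1539 and 943. Both change test and scaling together, and they went opposite ways. One Cx1 library held 2542 counts, and without libraries under 100000 counts 727 were higher and 175 lower. Further, 18 of 77 ribosomal protein genes and 10 of 14 mitochondrial models were higher in the C daughters but 4 and 2 with median-ratio scaling and 6 and 1 without those libraries. Ribosomal RNA averaged 4.45% of counts in Cx1 (range 1.13 to 13.1, n = 5) and 3.66% in Cx2 (1.32 to 5.71, n = 6), against 2.696% in D (1.03 to 4.78, n = 6) and 1.27% in P4 (0.68 to 2.42, n = 6). The mitochondrial share averaged 2.416% in Cx1, 2.415% in Cx2, 2.21% in D and 0.819% in P4.

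D and P4, the daughters of P3, were compared next. Several transcripts read higher in P4, the germline founder, than in its sister. D libraries were poorer, with a median of 1898 genes at 10 RPKM and 632339 counts, against 3197 and 1395568 in P4. A low value in D therefore cannot be told apart from missed detection. dnj-27 stood at 92.4 ± 137 RPKM in P4 (n = 6) against 0 counts in D, at least 178-fold higher, and brf-1, a subunit of the polymerase III factor TFIIIB, at 144 ± 147 against 0.2 ± 0.3. ZK652.6 stood at 236 ± 124 against 2.6 ± 5.1, F35G12.4 at 241 ± 223 against 4.9 ± 6.4, ent-1, a nucleoside transporter, at 566 ± 532 against 25.5 ± 31.6 and tbb-1, a beta-tubulin, at 489 ± 254 against 111 ± 84.1. On the D side sdz-1 stood at 1036 ± 1777 against 1.9 ± 2.0 RPKM (adjusted p = 0.00762). In the EMS and SKN-1-dependent list 2 of 15 were higher and 1 lower in D (3 and 2 over the list alone; set adjusted p = 0.026, but 0.298 with an estimated correlation). Mitochondrially encoded models were higher in D as a set (adjusted p = 0.000528, but 0.544 with an estimated correlation), with 1 of 14 passing and a mean mitochondrial share of 2.21% in D against 0.819% in P4, and total counts of D libraries ran down to 68516 against 1027727 in P4. The test called 46 genes higher and 86 lower in D. These counts became 83 and 49 with median-ratio scaling and 3 and 168 with limma. In simulation the test recovered 0% of the changed genes here. When cells were exchanged within embryos, 1 other grouping gave 148 calls against the real 132. DESeq2 called 697 and 626 and the earlier form 63, or 40 with the embryo as a block, and the count was 30 without embryo 2, 65 without embryo 7, 70 without embryo 1 and 72 without embryo 3 or 6. tbb-1 lost its call in most of these.

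In the AB lineage at the 16-cell stage the granddaughters of ABp were compared with those of ABa. edgeR called 0 of 8397 genes, limma 10, all lower on the ABp side, DESeq2 294 and the earlier form of the test 137, or 1 with the embryo as a block. In edgeR 505 genes had an unadjusted p under 0.05, and without embryo 7 edgeR called 1. The T-box factors tbx-38 and tbx-37, needed in ABa descendants and near-identical in sequence, read 350 ± 98.7 and 210 ± 70.5 RPKM in the ABa granddaughters (SD, n = 6) against 13.8 ± 32.9 and 30.6 ± 56.5 (adjusted p = 0.364 and 0.824). Early zygotic transcripts, a list that holds both, were lower on the ABp side as a set (adjusted p = 0.000135, and 0.0158 with an estimated correlation), with 1 of 8 lower over the list alone. hlh-27, a REF-1 family gene, read 94.0 ± 34.4 RPKM in ABarx, 74.8 ± 61.9 in ABplx and 38.8 ± 57.5 in ABprx, and was at 10 RPKM in all 6 ABarx embryos.

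Sister cells were compared in the other lineages as well. Of 19 genes called by edgeR, all lower in Ep than in Ea, sdz-21 met the naming rule, at 0.6 ± 0.7 (n = 6) against 46.0 ± 30.02 RPKM (n = 4, adjusted p = 0.019). The count was 1 without libraries under 100000 counts, 0 without embryo 2, 1 without embryo 8, 5 without embryo 3, 6 without embryo 6 and 12 without embryo 7. limma called 20 higher and 13 lower, and DESeq2 called 1113. The earlier form of the test called 8, or 2 with the embryo as a block. Between the 2 MS daughters B0035.6, chosen after its values were seen, was the single call; the count was 0 with the earlier form of the test and without embryo 1, 2, 3, 6 or 7, and DESeq2 called 954. The MS regulators were lower in MSx2 as a set (adjusted p = 0.0067, and 0.0374 with an estimated correlation), ceh-51 at 669 ± 661 (n = 6) against 1119 ± 382 RPKM (n = 5), with 0 of 5 passing. Between the C daughters all 36 calls were lower in Cx2, among them rpl-35, a ribosomal protein. The count fell to 0 without libraries under 100000 counts, 1 without embryo 8, 6 without embryo 3, 9 without embryo 2 or 6, 15 without embryo 7 and 0 with the embryo as a block, while DESeq2 called 949.

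Whether the E and MS difference itself changed from the 8- to the 16-cell stage was tested as an interaction. The test found that 5 genes moved toward E and 2 toward MS among 6551. Y65A5A.1 stood at 788 ± 899 RPKM in the E daughters (n = 6) against 0.4 ± 0.6 in the MS daughters (interaction adjusted p = 0.000187) and prx-3, a peroxisome assembly factor, at 905 ± 805 against 1.3 ± 3.0 (adjusted p = 0.00243). ten-1 (adjusted p = 0.0224) and lon-2, a glypican at 24.1 ± 55.4 against 531 ± 501 RPKM (adjusted p = 0.0313), moved toward MS. At the 8-cell stage Y65A5A.1 stood at 0 in E and 64.5 ± 144 RPKM in MS (n = 5), prx-3 at 0 and 13.2 ± 29.5, ten-1 at 22.2 ± 42.2 and 1.1 ± 1.2, and lon-2 at 45.7 ± 83.2 and 0.2 ± 0.4. For Y65A5A.1 and prx-3 a single MS library reached 10 RPKM, and the calls were lost without its embryo (8-cell embryo 3 and 8-cell embryo 6). The calls of ten-1 and lon-2 were lost without 8-cell embryo 4 (adjusted p = 0.184 and 0.102), among others. The values of prx-3 and lon-2 overlap between the E and MS daughters of the 16-cell stage, so these were chosen after their values were seen. The same 8-cell MS library with 70.3% ribosomal RNA enters here, the median gene shifted by -0.56, limma called 6 and 5, and the count was 1 without 8-cell embryo 3, 3 without 8-cell embryo 4 and up to 10 otherwise. The earlier form of the test with the embryo as a block called 5.

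**Figure D4:**
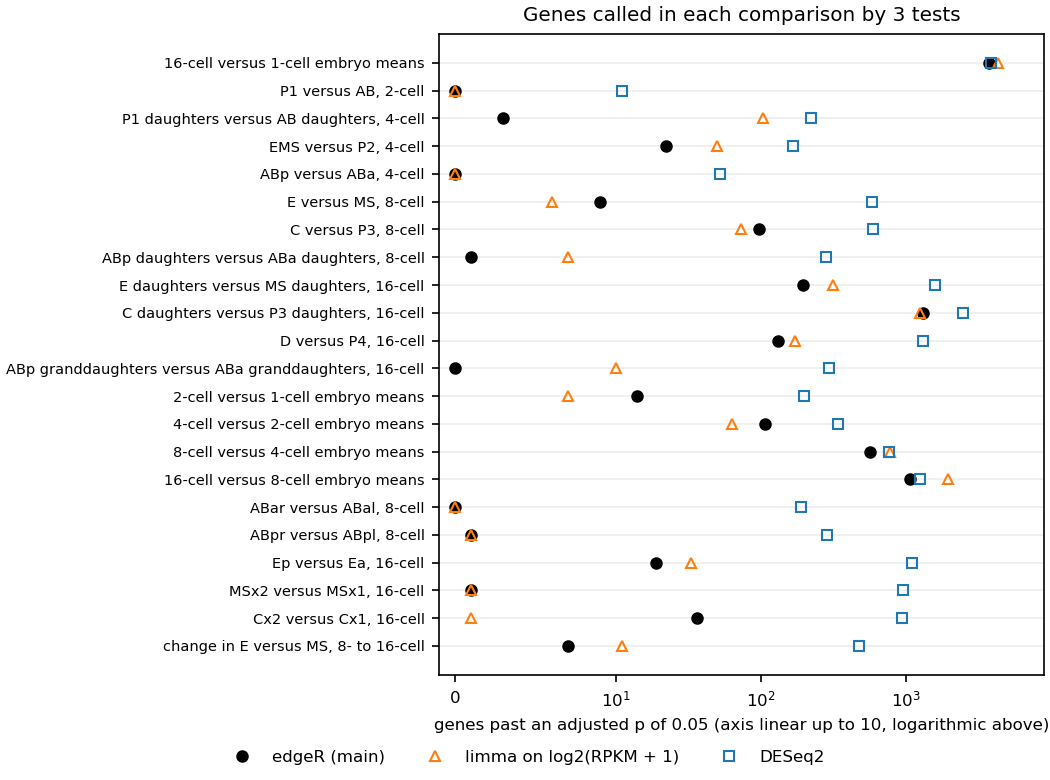
Genes past an adjusted p of 0.05 (horizontal axis, linear up to 10 and logarithmic above) in each comparison (vertical axis); each point is the count from 1 of 3 tests, edgeR, limma on log2(RPKM + 1) or DESeq2, over the embryos of that comparison. edgeR calls 3748 genes between the 16- and 1-cell stages and 1311 between the C and P3 daughters, and DESeq2 calls more than edgeR in all 22 comparisons.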

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

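Chosen only after the result was seen were the test of depth for genes per cell, the 2 tests on the C and P3 daughters, the test of scaling for X-linked genes and all counts of other splits; the tests of loss from the whole embryo, of lineages and of the level of X-linked genes were chosen before.

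Fewer genes were seen per cell at the 16-cell than at the 1-cell stage, and 3 explanations were tested. Depth alone is argued against, since at 400000 counts per cell the 16-cell value was still lower (difference -47.53%, two-sided exact permutation p = 0.002165, 6 against 5 embryos). For loss from the whole embryo, 4724 genes at 10 RPKM in every 1-cell library were followed. Of these 55.3% ± 5.64 were lost per cell and 17.5% ± 2.35 from the mean of an embryo's cells. The second share was 31.64% of the first (SD 2.132, 6 embryos), under the bound set in advance. Most of these genes thus still averaged 10 RPKM over an embryo's cells. A mean over many cells reaches that level when a few cells are high, and a partial fall is not counted as loss. The test therefore cannot decide whether transcripts declined in the whole embryo. Whether different lineages keep different transcripts cannot be told apart from other reasons: detection disagreed less between 2 cells of 1 AB group (0.546 of what independent detection gives) than between AB and other cells (0.663), a ratio of 0.824 (SD 0.0303) that lies between the bounds of 0.7 and 0.9 set in advance, while cells of different AB groups gave 0.5445. A lower yield from smaller cells was not tested and stays open.

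The C daughters gave more calls against the P3 daughters than any other cell pair, most higher in the C daughters. Libraries under 100000 counts are argued against as the sole source: 854 calls (65.14%) held without them. Calls higher in the P3 daughters fell from 393 to 175. Whether the direction comes from the scaling between libraries cannot be told apart from other reasons: with TMM 918 of 1311 calls were higher in the C daughters and with median-ratio scaling 47.74% were, but 62.01% were with DESeq2, which changes test and scaling together (1539 higher and 943 lower), and limma, which does so too, gave 459 and 802. A difference between the C and the germline lineage itself, and names given from these same transcriptomes, stay open as untested explanations.

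X-linked genes were rarely among those lower at the 16-cell than at the 1-cell stage, 51 of 802 (6.36%) against 19.2% of 6712 autosomal genes. Their lower level in the egg (median 23.6 against 56 RPKM) is argued against as the whole reason, since autosomal genes drawn at matched levels gave a mean of 11.56% (95% of 10000 draws between 9.73 and 13.47, lowest 7.98). The scaling is argued against as well, since the X-linked share was 34.9% of the autosomal share with median-ratio scaling and 46.57% with limma on RPKM, the higher of the 2. No biological explanation was tested.

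For each count of calls, embryos or cells were regrouped at random and the test repeated. Fewer than 1 in 20 splits gave as many calls in 12 of the 22 comparisons. In the 5 comparisons of stages, whose groups do not rest on the transcriptomes, 1 of 40 splits, the real one, gave as many. Chance is argued against as the sole source for the 16- versus 1-cell stage (3748 calls, highest other split 2). The same holds for 8- versus 4-cell (568 and 63) and 16- versus 8-cell (1065 and 127). For 2- versus 1-cell (14 and 12) and 4- versus 2-cell (107 and 87) another split came close to the real count. With 40 splits chance is not excluded for them. The other 7 compare named cells. Since most names were given from these same transcriptomes, a real grouping that gives more calls than a random one is partly built in, and these splits do not exclude chance. The real grouping alone gave as many among 40 splits for C versus P3 (97 and 52) and the E and MS interaction (7 and 4). It also did among 100 splits for EMS versus P2 (22 and 6) and among 21 for the E versus MS daughters (196 and 15), the C versus P3 daughters (1311 and 236) and D versus P4 (132 and 104). For the P1 versus AB daughters 3 of 100 splits gave 3 calls or more, and 1 gave 54, many times the real count, which may point to a structure of the samples other than the lineage; what that split follows was not tested.

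In 6 further comparisons of named cells 1 in 20 splits or more did so, and chance cannot be excluded. As many calls came from 11 of 40 splits for E versus MS (9 calls, highest other 21), 10 of 40 for the ABp versus ABa daughters (1 and 4), 3 of 40 for ABpr versus ABpl (1 and 1), 4 of 21 for Ep versus Ea (19 and 21), 9 of 21 for MSx2 versus MSx1 (1 and 4) and 11 of 21 for Cx2 versus Cx1 (36 and 85). In 4 comparisons the real count is 0, which every split reaches by construction, so these say nothing of chance: 100 of 100 for P1 versus AB (highest other 1) and for ABp versus ABa (2), 40 of 40 for ABar versus ABal (2) and 21 of 21 for the ABp versus ABa granddaughters (1).

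Splits that exchange cells only within an embryo were counted as well, and the given names limit these in the same way. Of 21 such splits 1, the real one, gave as many calls for the E versus MS daughters (highest other 56), the C versus P3 daughters (898) and the interaction (5), but 2 of 21 did for D versus P4, where another gave 148 calls against 132, so that chance is not excluded there when cells are exchanged within embryos. Where only 16 paired splits exist a share under 1 in 20 cannot be reached; real count and highest other were 3 and 1 for the P1 versus AB daughters, 22 and 1 for EMS versus P2, 97 and 49 for C versus P3, 9 and 15 for E versus MS, 1 and 1 for the ABp versus ABa daughters, 1 and 1 for ABpr versus ABpl, 1 and 3 for MSx2 versus MSx1 and 36 and 44 for Cx2 versus Cx1, and with 8 paired splits 19 and 18 for Ep versus Ea.

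In 18 of 96 sets of 4 to 10 libraries of 1 group, 1 library stood apart by Dixon's test at 95%; chance gives about 1 in 20. Shares below have 95% Wilson intervals. Ribosomal RNA was 70.3% (69.9 to 70.7) in MS of embryo 1 (others up to 2.22), 13.14% (11.9 to 14.51) in Cx1 of embryo 1 (3.27), 8.773% (8.55 to 9.01) in Ea of embryo 8 (2.51), 8.609% (8.5 to 8.72) in 1 MSx2 cell of embryo 3 (3.64), 7.269% (7.21 to 7.33) in MSx1 of embryo 7 (2.15), 5.153% (5.11 to 5.2) in ABpr of embryo 1 (1.58), 4.733% (4.7 to 4.77) in ABar of embryo 6 (1.71), 3.399% (3.37 to 3.43) in C of embryo 6 (1.03) and 2.614% (2.59 to 2.64) in P1 of embryo 5 (0.341). Mitochondrial RNA was 8.316% (8.24 to 8.4) in 1 MSx2 cell of embryo 1 (3.27), 5.861% (5.71 to 6.01) in Cx1 of embryo 8 (2.24), 4.353% (4.29 to 4.41) in 1 ABalx cell of embryo 1 (1.95), 2.808% (2.79 to 2.83) in ABp of embryo 5 (0.953) and 1.507% (1.49 to 1.52) in P2 of embryo 5 (0.674). Genes at 10 RPKM were 1656 in an ABalx cell of embryo 1 (others from 2960) and 3991 in P2 of embryo 4 (from 4903). Total counts were 3790868 in ABa of embryo 1 (others up to 2230189) and 3032810 in ABpl of embryo 6 (up to 1810872).

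In 10 of 74 pairs of a named gene and a comparison 1 embryo stood apart on the side where the gene is higher. The lowest values were T14B4.5 at 1.85 RPKM in 1-cell embryo 4 (others 55 to 103), Y75B12A.2 at 229.1 in EMS of embryo 5 (386 to 473) and 57.28 in the mean of that embryo's cells (96.7 to 118), F55D12.5 at 2.57 in P2 of embryo 3 (36.7 to 83.6), ZK673.5 at 67.44 in C of embryo 6 (364 to 674), F37C4.6 at 9.315 in the E daughters of embryo 8 (216 to 369), ZK652.6 at 36.7 in P4 of embryo 8 (174 to 369), med-2 at 3.312 in the mean of 4-cell embryo 5 (36.2 to 60.8) and sdz-21 at 2.94 in Ea of embryo 1 (48.3 to 68.9). C05D12.5 was highest, at 3525 RPKM, in the C daughters of embryo 7 (337 to 622).

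The difference between E and MS changed from the 8- to the 16-cell stage for 7 genes by a test of the difference itself (edgeR quasi-likelihood, Benjamini-Hochberg adjusted). Y65A5A.1 (adjusted p = 0.000187) and ten-1 (0.02236) meet the naming rule; prx-3 (0.002434) and lon-2 (0.03129), whose values overlap between the E and MS daughters, were chosen after their values were seen.

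Lineage regulators were seen in cells with no identity in the labels. Of 45 such 16-cell libraries, the number at 25 RPKM or more with over 3 counts was 7 for end-1 (77.7 to 2132 RPKM), 8 for elt-7 (111 to 2759), 4 for tbx-35 (32.7 to 561), 11 for ceh-51 (141 to 4351), 6 for hlh-1 (32 to 4459) and 11 for tbx-37 (28.4 to 900). Among 90 labelled 16-cell libraries 8, 9, 9, 18, 8 and 22 reached that level.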

How the results depend on the processing

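DESeq2, the earlier quasi-likelihood form and leaving out libraries under 100000 counts were chosen after the data were seen. So was running the block with the earlier form or limma. Limma was the test written in advance, while the edgeR form of the main test was chosen after calls of other forms had been seen. The other alternatives were planned. The 3748 calls between the 16- and the 1-cell stage stayed within 1.5 times under every alternative run. The counts that did not are given below, each beside its main count; the cause was not tested unless fewer genes or fewer libraries are named.

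DESeq2 called more genes than edgeR in every comparison, by over 1.5 times in these: 11 for P1 versus AB (0 with edgeR), 221 for the P1 versus AB daughters (3), 168 for EMS versus P2 (22), 52 for ABp versus ABa (0), 582 for E versus MS (9), 596 for C versus P3 (97), 281 for the ABp versus ABa daughters (1), 1596 for the E versus MS daughters (196), 2482 for the C versus P3 daughters (1311), 1323 for D versus P4 (132), 294 for the ABp versus ABa granddaughters (0), 200 for 2- versus 1-cell (14), 341 for 4- versus 2-cell (107), 189 for ABar versus ABal (0), 288 for ABpr versus ABpl (1), 1113 for Ep versus Ea (19), 954 for MSx2 versus MSx1 (1), 949 for Cx2 versus Cx1 (36) and 475 for the E and MS interaction (7). On simulated counts more of its calls were false, 36 of 193 for 16- versus 1-cell, 24 of 180 for P1 versus AB and 44 of 197 for the P1 versus AB daughters, against 8 of 151, 7 of 144 and 13 of 143 with edgeR; other comparisons were not simulated with DESeq2.

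With limma on log2(RPKM + 1) there were 103 calls for the P1 versus AB daughters, 50 for EMS versus P2, 7 for the ABp versus ABa daughters, 315 for the E versus MS daughters, 10 for the ABp versus ABa granddaughters, 7 for 2- versus 1-cell, 63 for 4- versus 2-cell, 1960 for 16- versus 8-cell (1065 in the main test), 33 for Ep versus Ea, 1 for Cx2 versus Cx1 and 11 for the interaction. A pseudocount of 10 RPKM in limma gave 134, 55, 7, 338, 10, 22, 40, 1971, 40, 1 and 17 for these, and 5 for E versus MS, 251 for D versus P4, 0 for ABpr versus ABpl and 5 for MSx2 versus MSx1. Array quality weights in limma gave 1 for P1 versus AB, 143 for the P1 versus AB daughters, 63 for EMS versus P2, 4 for E versus MS, 6 for the ABp versus ABa daughters, 312 for the E versus MS daughters, 13 for the ABp versus ABa granddaughters, 1248 for 2- versus 1-cell, 889 for 8- versus 4-cell (568), 1 for Cx2 versus Cx1 and 25 for the interaction. Limma turned the balance of directions, higher and lower, from 2373 and 1375 to 1689 and 2630 for 16- versus 1-cell, from 617 and 448 to 653 and 1307 for 16- versus 8-cell, from 918 and 393 to 459 and 802 for the C versus P3 daughters, from 2 and 7 to 6 and 0 for E versus MS and from 0 and 19 to 20 and 13 for Ep versus Ea. The pseudocount of 10 RPKM also turned it from 94 and 3 to 31 and 41 for C versus P3 and from 475 and 93 to 406 and 445 for 8- versus 4-cell.

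The earlier quasi-likelihood form gave 5 calls for E versus MS, 57 for C versus P3, 0 for the ABp versus ABa daughters, 699 for the E versus MS daughters, 2055 for the C versus P3 daughters, 63 for D versus P4, 137 for the ABp versus ABa granddaughters, 1 for 2- versus 1-cell, 8 for Ep versus Ea, 0 for MSx2 versus MSx1, 17 for Cx2 versus Cx1 and 12 for the interaction. Median-ratio scaling gave 16 for the P1 versus AB daughters, 20 for E versus MS and 12 for Cx2 versus Cx1. No filter on low values, which tests more genes, gave 8 for the P1 versus AB daughters, 49 for E versus MS, 26 for the ABp versus ABa daughters, 2 for the ABp versus ABa granddaughters, 2 for 2- versus 1-cell, 323 for 8- versus 4-cell, 671 for 16- versus 8-cell, 2 for ABar versus ABal, 8 for ABpr versus ABpl, 43 for Ep versus Ea, 9 for MSx2 versus MSx1 and 46 for the interaction. Without libraries under 100000 counts, with fewer libraries, there were 3 for E versus MS, 1 for Ep versus Ea and 0 for Cx2 versus Cx1. There were 2 for 2- versus 1-cell, where neither stage lost a library (lowest total 1160741 counts). Only later stages of the shared fit did, and the cause was not tested. The 2 complete 16-cell embryos alone gave 526 for 16- versus 8-cell.

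With the embryo as a block there were 65 calls for the P1 versus AB daughters; P1 versus AB, EMS versus P2 and ABp versus ABa stayed within 1.5 times. At the 8- and 16-cell stages the block in the earlier form gave 0 for E versus MS, 54 for C versus P3, 0 for the ABp versus ABa daughters, 338 for the E versus MS daughters, 40 for D versus P4, 1 for the ABp versus ABa granddaughters, 0 for ABpr versus ABpl, 2 for Ep versus Ea, 0 for MSx2 versus MSx1 and 0 for Cx2 versus Cx1. The block in limma gave 205 for the P1 versus AB daughters, 71 for EMS versus P2, 7 for the ABp versus ABa daughters, 328 for the E versus MS daughters, 209 for D versus P4, 10 for the ABp versus ABa granddaughters, 31 for Ep versus Ea and 0 for Cx2 versus Cx1. At these later stages the form changes together with the block: within the earlier form C versus P3 went from 57 to 54 with the block, and the interaction from 12 to 5. Of 42 list tests of cell comparisons past the threshold 38 passed with the block, and 1 passed only with it.

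Leaving out 1 embryo at a time gave 0 to 69 for the P1 versus AB daughters, 1 to 31 for EMS versus P2, 0 to 1 for ABp versus ABa, 0 to 12 for E versus MS, 37 to 93 for C versus P3, 0 to 2 for the ABp versus ABa daughters, 108 to 152 for the E versus MS daughters, 30 to 163 for D versus P4, 0 to 1 for the ABp versus ABa granddaughters, 0 to 60 for 2- versus 1-cell, 375 to 646 for 8- versus 4-cell, 0 to 1 for ABpr versus ABpl, 0 to 17 for Ep versus Ea, 0 to 1 for MSx2 versus MSx1, 1 to 24 for Cx2 versus Cx1 and 1 to 10 for the interaction.

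Of 74 list tests past the threshold with the preset correlation, 23 passed with an estimated one. Among named genes the direction and the call held in 257 of 270 cases with DESeq2, 251 with median-ratio scaling, 234 with no filter, 228 with the earlier form, 217 with weights, 216 with limma, 209 with the larger pseudocount, 71 of 90 with complete embryos, 8 of 11, 77 of 114 and 90 of 125 with the block (chosen form, earlier form, limma), 233 of 269 without libraries under 100000 counts and 1892 of 2283 with 1 embryo left out; the others kept their direction and lost the call, except 8. In the C versus P3 daughters the log2 fold change turned for rpl-35 (-0.52 without libraries under 100000 counts; -0.62 to 3.55 with 1 embryo left out, lowest without embryo 8), MTCE.12 (-0.075; -0.49 to 2.62) and MTCE.31 (-0.075 to 2.08 with 1 embryo left out). In D versus P4 it turned without embryo 2 for mcm-6 (-0.42 to 3.96) and sdz-30 (-0.73 to 5.90), and in Ep versus Ea for rps-0 (0.55 without libraries under 100000 counts). Depth limits groups with shallow libraries: the lowest totals are 2542 counts in Cx1, 58056 in Ea, 58985 in MS and 68516 in D.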

Other observations

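Genes of the cell cycle and of several families also changed between the 1- and the 16-cell stage. A member absent from the egg could not be called lower here either, as it passed the filter only through later stages. Of 31 cell cycle genes 20 rose and 5 fell, and as many adjusted over the list alone (15 to 20 higher and 5 to 7 lower under other scalings and tools), while the list as a set missed the threshold (adjusted p = 0.0534, and 0.765 with an estimated correlation). The B-type cyclins cyb-1 and cyb-3 went from 321 ± 56.0 and 711 ± 157 RPKM (SD, n = 5 embryos) to 762 ± 114 and 1775 ± 388 (n = 6), mcm-7, a subunit of the replicative helicase, from 273 ± 16.7 to 547 ± 76.2, and bub-1, a kinetochore kinase, from 46.7 ± 11.2 to 177 ± 57.5. Homeobox genes of the ceh family rose in 11 of 16 cases (Fisher's exact test, adjusted p = 0.0127 over 54 family tests; 10 or 11 under other scalings and tools), skr genes in 11 of 17 (adjusted p = 0.0229; 10 or 11) and fbxc F-box genes in 20 of 30 (adjusted p = 0.000426; 19 to 21). Of 25 vps genes, which act in vesicle sorting, 10 fell (adjusted p = 0.0401; 10 to 13 fell), and 14 of 22 nucleoporin genes rose (adjusted p = 0.0107), but 6 rose and 5 fell with limma.

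Chromosome X held few genes that fell from the 1- to the 16-cell stage: 6.36% of 802 were lower, against 17.4% to 20.6% on the autosomes, and 33.9% were higher, against 25.7% to 33.2%. Between the C and the P3 daughters 15.4% of 892 X-linked genes were higher in the C daughters, against 8.76% to 12.9% on the autosomes, and 1.91% were lower, against 4.68% to 5.81%. With median-ratio scaling 93 X-linked genes were higher and 30 lower there (137 and 17 with TMM), against 478 and 642 autosomal genes (708 and 369).

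Of 15 polarity genes 4 rose and 5 fell from the 1- to the 16-cell stage (set adjusted p = 0.269; 1 and 8 with limma), of 7 heat shock genes 3 rose and 0 fell (0.637; 3 and 2 with limma), and of 8 C and D lineage regulators 1 rose and 2 fell (0.920). The last list was lower in the ABp than in the ABa granddaughters as a set (adjusted p = 0.00769, but 0.1 with an estimated correlation) with 0 of 9 genes passing.

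Markers of other cell types were low with exceptions. Of 46 sperm genes 4 reached a mean of 10 RPKM in some group, msp-76 being highest at 28.6 RPKM in MSx1, of 9 adult intestine genes 1 did, vit-5 at 55.9 in MS, and 0 of 7 muscle and 0 of 7 epidermis genes did, with mup-2 at 3.4 in AB and col-12 at 0.908 in P1 the highest. Of 8 neuron genes 5 did, snb-1 being highest at 661 RPKM in Ep and 315 in P0, and of 5 gonadal sheath genes 3 did, lim-7 at 48.8 in ABalx.

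The 45 unassigned 16-cell libraries had a median of 643176 counts, against 1214134 in labelled ones, the 8 unassigned 8-cell libraries 192318 against 1579928, and the 1-cell library 2246438. Ribosomal RNA was 0.586% ± 0.324 of counts at the 1-cell, 0.561% ± 0.632 at the 2-cell, 0.944% ± 0.48 at the 4-cell, 3.02% ± 4.17 at the 8-cell and 2.7% ± 0.794 at the 16-cell stage (SD, 5 embryos each, 6 at the last). The 1- and 2-cell values gave a two-sided exact permutation p of 0.9603, and the later stages were not tested against the first.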
